A study of Mus musculus with 8 samples.

How the data were processed

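RNA of mouse oocytes and cultured pluripotent cells was sequenced as stranded paired-end libraries from total RNA extracted with TRIzol. Whether the kit used included a poly(A) selection is not given in the sources used here. The 8 libraries fall into 4 groups of 2: oocytes at the germinal vesicle stage (GV), oocytes at metaphase II (MII), embryonic stem cells (ESC) and in vitro epiblast cells (EpiC). Per the labels, the authors primed mice with 5 units of PMSG 48 h before an injection that is not named, and took GV oocytes into medium with 2 µM milrinone. The label of the MII samples repeats the growth protocol of the GV samples and gives no maturation step. Per the labels, ESC were grown in 15% FBS with LIF and the 2 inhibitors PD0325901 and CHIR99021. EpiC were plated for 24 h, LIF and inhibitors were withdrawn, and cells were collected about 56 h later. The labels do not say whether replicates came from separate animals or cultures, so each p measures only the spread between these samples.

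The deposited tables hold estimated counts per transcript, which the authors made with kallisto 0.43 on the mm10 build per the submitters' processing notes. The same deposited tables hold TPM, the share of each of all listed transcripts after division by its length, with the effective length of each transcript. Each table listed 117667 transcripts of 48440 genes, of which 21989 had a protein-coding transcript. Symbols came from the transcript names in the tables, and gene positions came from GENCODE M21 on GRCm38. Total estimated counts ran from 47463546 in EpiC replicate 1 to 196788239 in MII replicate 2. Intervals, floors and p-values cover counting error and the spread between libraries, and not the error of assigning reads to transcripts, because the tables hold no bootstrap values.

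Estimated counts were summed per gene and rounded. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 25045 genes, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries with 4 residual degrees of freedom and robust estimates. Each contrast was tested with glmQLFTest, and Benjamini-Hochberg adjustment ran over the genes of that contrast at a threshold of 0.05. All adjusted p-values of single genes are from this edgeR quasi-likelihood test. The contrasts were GV against ESC, MII against EpiC, MII against GV, EpiC against ESC, and the difference of the first pair, which equals the EpiC against ESC change minus the MII against GV change. Log2 fold changes are given ± SE and TPM means ± SD (n = 2). This SE is approximate, the absolute log2 fold change over the square root of the quasi-likelihood F statistic. It was not taken from the model fit, and was not checked where a group lies near 0 counts. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library. Relative to TMM, log2(TPM + 1) moved the median log2 fold change of all genes by −0.87 for MII against GV, −1.09 for MII against EpiC and −0.27 for GV against ESC. Relative log expression moved it by 0.21 for MII against GV and 0.18 for MII against EpiC. Directions are therefore relative to the bulk of mRNAs, and do not give amounts per cell. A log2 fold change, made on TMM-scaled counts, can also differ from the ratio of the TPM means printed beside it. No spike-in or RNA mass per cell was given in the sources used here.

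Transcript usage was tested with diffSpliceDGE of edgeR on filtered transcripts of 11953 genes, with Simes p-values per gene. Shares are the transcript's TPM over the TPM of its gene. Lists of genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, from limma 3.58.1. Adjustment ran over 92 tests, 23 lists in 4 comparisons. The lists covered microRNA biogenesis, RISC and Argonaute partners, deadenylation with decapping and mRNA storage, the piRNA pathway, oocyte markers, the meiotic cell cycle, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation and mitochondrially encoded mRNAs. They also covered naive pluripotency, general pluripotency, formative and primed epiblast, germ layers and mesendoderm, extraembryonic endoderm and trophoblast, ERK targets, Wnt targets, 2-cell-like genes, DNA methylation, reported targets of the microRNA-290 and microRNA-302 families, reported let-7 targets, cumulus and granulosa cells, fibroblast feeder cells, and blood with macrophages. Msy2 of the storage list was not found under that symbol.

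Lists, contrasts, alternatives and the rule for naming genes were fixed before the data were examined. Members of the microRNA biogenesis and RISC lists may be named, as may Ago2, Dicer1, Zp3, Pou5f1, Nanog and Fgf5. From every other list, up to 3 called members per direction with the largest fold changes may be named. The rule also admits the 8 highest and the 8 lowest fold changes among called protein-coding genes with a mean of at least 20 TPM and no overlap between the libraries of the groups, leaving out gene models with a clone or Gm name. For transcripts it admits those of the Argonaute, Dicer1, Drosha, Dgcr8 and Tnrc6 genes with a share of at least 10%. It also admits the 3 genes per contrast with the lowest p among those whose share moved by at least 30 points. Names outside this rule are stated as such.

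The steps were tested on simulated data. Counts were simulated with 200 genes changed 1.5-, 2- or 4-fold, alongside the genes of the lists planted at 2-fold that are described below. Of the 200, the test recovered 0 in 3 contrasts and 1.5% of those changed 4-fold for MII against GV. After this was seen, larger folds were simulated. With 50 genes per fold, 30%, 18%, 28% and 20% of 4-fold changes were recovered in the order of the contrasts, and 78%, 86%, 88% and 84% of 32-fold changes. Of the unchanged genes, 12, 4, 7 and 10 were called. A dense simulation, also added then, set 12522 genes equal between groups. Of its calls, 2.54%, 2.04%, 1.78% and 2.75% were false when genes were equal on the normalised scale. When genes were equal on raw totals, 2.83%, 19.4%, 4.29% and 3.65% were false. Camera with the preset correlation called 10 of 10 lists planted at 2-fold in each contrast, and 1 of 20 null lists for EpiC against ESC. With the estimated correlation it called 9, 9, 10 and 3 of the planted lists. Fry called as many, with 1 null list for GV against ESC. Genes were drawn independently in these simulations, so they cannot test the preset correlation for lists whose members vary together. The estimated correlation of the real ribosomal protein list was 0.614 for GV against ESC. Of 200 swapped transcript pairs, 28, 29, 27 and 22 were recovered, with 10, 19, 20 and 14 unchanged genes called. In the dense form, 4.57%, 5.54%, 6.41% and 21.4% of the transcript calls were false.

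Sequence words of 7 bases were searched in 3′ UTRs of at least 100 bases, 1 transcript per gene, for 11551 genes. The log2 fold change was regressed on the presence of a word with UTR length and GC content and their squares as covariates, and the coefficient was set against up to 200 permuted words of the same letters. A planted coefficient of 0.3 was called in 32.2% of simulations and a coefficient of 0 in 0.312%. These simulations pooled all words and contrasts and shuffled the fold changes over genes. The polyadenylation elements TTTTAAT and TTTTATT, with 14 and 4 permuted words, could not be called in them. The rates therefore do not apply to single words or to the real data. Alternatives were relative log expression size factors, DESeq2 1.42.0, no count filter, a fit on the compared groups alone, a block for the replicate number, an offset for transcript length, limma on log2(TPM + 1), a test against a fold of 2, omission of mitochondrial and ribosomal RNA genes, and omission of each library in turn. For transcripts they were limma voom with diffSplice and a minimum share of 5% in 2 libraries. A run on protein-coding genes alone, without mitochondrially encoded and replication histone genes, was chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made tables and figures.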

Results

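Expression was measured by RNA sequencing in 8 mouse libraries of 4 groups, 2 libraries each. GV oocytes are arrested before the meiotic divisions, and MII oocytes are arrested at the metaphase of the second division. ESC are pluripotent cells held in LIF with inhibitors of MEK and GSK3, and EpiC are cells that left this condition toward a postimplantation epiblast state. Total estimated counts were 79465769 and 187501275 in the GV libraries, 75157505 and 196788239 in MII, 50216249 and 166400271 in ESC, and 47463546 and 116034226 in EpiC. Replicate 2 was deeper than replicate 1 by 2.36 to 3.31 times in every group. Across genes, which are not independent replicates, the correlation between the replicates of a group was 0.949 for GV, 0.964 for MII, 0.934 for ESC and 0.892 for EpiC. ESC and EpiC libraries of the same replicate number correlated at 0.8829 for replicate 1 and 0.8935 for replicate 2, close to the value within EpiC. Gm42418, a gene model on chromosome 17 from 39846958 to 39848788 known to collect reads of ribosomal RNA, took 1.66%, 3.03%, 14.7% and 22.7% of the counts in replicate 2 of GV, MII, ESC and EpiC. Mitochondrially encoded genes took 0.746% and 0.819% of the counts in GV, and between 1.93% and 3.68% in the other 6 libraries. TMM factors were 0.422 and 0.405 for the MII libraries and between 1.07 and 1.58 for the other 6.

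The GV against ESC comparison asks how oocytes before maturation differ from pluripotent cells in the genes that make and use microRNAs. GV oocytes held little mRNA of Ago2, the Argonaute that slices its targets, and much mRNA of Dicer1, the enzyme that cuts microRNA precursors. Ago2 (ENSMUSG00000036698.10, GRCm38 chromosome 15, 73095844 to 73184935) measured 4.56 ± 1.4 TPM in GV and 50.7 ± 4.23 TPM in ESC (SD, n = 2), a log2 fold change of −3.17 ± 0.35 (SE; adjusted p = 9.4e-05). Dicer1 (ENSMUSG00000041415.9, chromosome 12, 104687742 to 104751952) measured 70.8 ± 49.4 TPM in GV and 15.5 ± 1.97 TPM in ESC, a log2 fold change of 2.49 ± 0.49 (adjusted p = 0.00226). Ago1 fell by 5.6 on the log2 scale, from 35.7 ± 5.27 TPM in ESC to 0.507 ± 0.345 TPM in GV.

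Of the 16 measured members of the RISC list, 2 rose in GV, 8 fell and 6 did not pass (camera adjusted p = 0.072, and 0.0376 without ESC replicate 2). Tnrc6a, a scaffold that Argonautes recruit, fell by 2.44 on the log2 scale, and the LIM-domain partner Ajuba by 7.94. Its relative Limd1 rose, with a log2 fold change of 2.54 ± 0.38. The helicase Mov10 fell by 2.68, but its call was lost without GV replicate 1, at −2.19. Fxr2, an RNA-binding relative of Fmr1, rose with 1.31 ± 0.39, and this call was lost without GV replicate 2 (1.14), ESC replicate 1 (1.28) or ESC replicate 2 (1.34), with the length offset (0.9) and with limma on log2(TPM + 1) (0.6). Ago3 measured 60.7 ± 10.2 TPM in GV and 4.93 ± 1.77 TPM in ESC, while the log2 fold change of its counts was 1.06 ± 0.47 (adjusted p = 0.0784). It passed with an offset for transcript length (3.9), with limma on log2(TPM + 1) (3.4), without a count filter (1.33) and on the compared groups alone (1.25). Its long coding transcript Ago3-001 measured 2.69 ± 1.63 TPM in GV and 2.56 ± 0.825 TPM in ESC. Ago3-004 and Ago3-006, annotated as noncoding, measured 25.6 ± 7.67 and 24.1 ± 0.33 TPM in GV. In ESC they measured 1.07 ± 0.393 and 0.485 ± 0.0956 TPM. The higher TPM of the gene in GV therefore does not show more coding mRNA. Ago4 measured 0.379 ± 0.0822 TPM in GV and 0.774 ± 0.328 TPM in ESC.

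Of the 17 members of the microRNA biogenesis list, 3 rose, 8 fell and 6 did not pass (camera adjusted p = 0.125). Tarbp2, the RNA-binding partner of Dicer1, rose with a log2 fold change of 1.32 ± 0.42, from 69.6 ± 4.3 to 154 ± 37.8 TPM. The call of Tarbp2 was lost without GV replicate 2 (0.87), ESC replicate 1 (1.26) or ESC replicate 2 (1.38). Dgcr8, the nuclear partner of Drosha, fell by 1.46, and lost its call without GV replicate 1, at −1.18. Ran fell by 3.12, the uridylyltransferase Zcchc11 by 3.57 and Trim71 by 3.72. Drosha measured 53.3 ± 23.1 TPM in GV and 60.8 ± 22.2 TPM in ESC (log2 fold change 0.09 ± 0.48, adjusted p = 0.882). Xpo5, the export receptor of precursors, had a log2 fold change of −0.81 ± 0.43 (adjusted p = 0.128), which passed with a replicate block (−0.82).

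**Figure D1:**
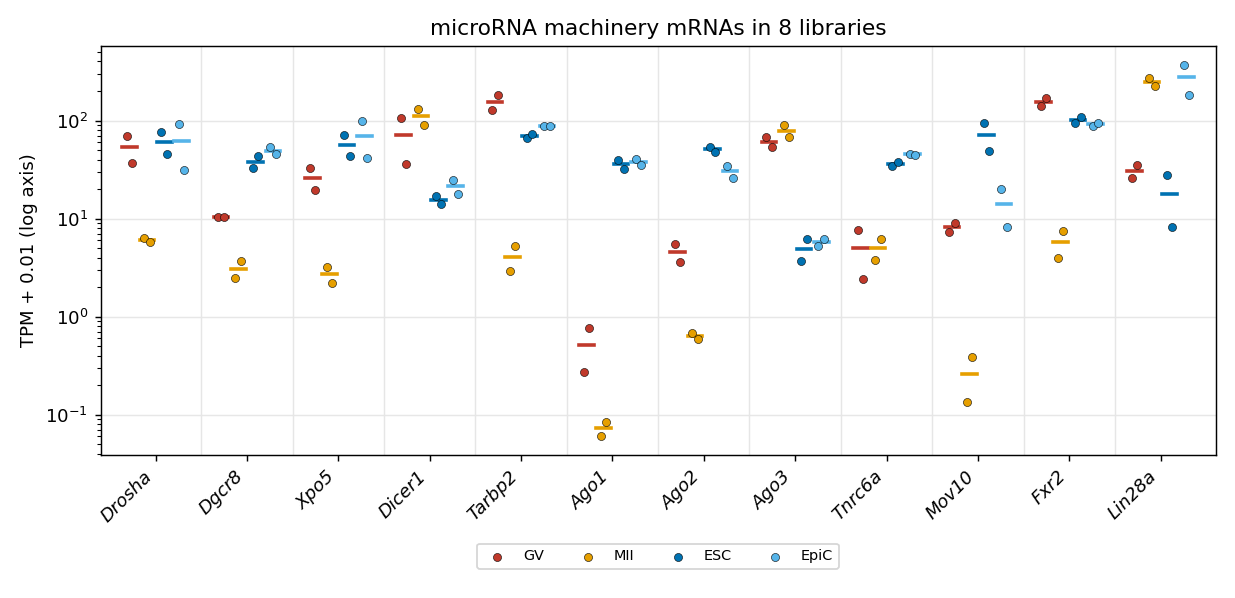
TPM of microRNA machinery genes in the 8 libraries on a log axis, with points for libraries and bars for group means. Ago2 lies at 4.56 TPM in GV and 50.7 TPM in ESC, and Dicer1 at 70.8 and 15.5 TPM.

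Germline groups were higher in GV oocytes. Of 28 oocyte markers, 25 rose and 3 did not pass (camera adjusted p = 3.4e-27, and adjusted p = 0.248 with an estimated correlation). Oosp1 measured 3350 ± 568 TPM against 0 in both ESC libraries, at least 51000-fold higher, and H1foo, the oocyte linker histone, 5640 ± 2060 TPM against 0.0324 ± 0.0458 TPM. Zp3, a coat protein of the egg, had a log2 fold change of 9.06 ± 0.76. Of 18 piRNA pathway genes, 15 rose and 3 did not pass (camera adjusted p = 3.08e-09, and adjusted p = 0.523 with an estimated correlation), among them Gtsf1 with 9.38 ± 0.57 and Tdrd1 with 9.46 ± 0.85. Of 27 meiotic cell cycle genes, 16 rose and 4 fell (adjusted p = 0.000817, and adjusted p = 0.666 with an estimated correlation). The kinase Wee2 rose by a log2 fold change of 16.95 ± 0.71, and the cohesin Rec8 fell by 9.17. In the list of deadenylation, decapping and mRNA storage, 21 of 37 genes rose and 9 fell (adjusted p = 0.000449, and adjusted p = 0.665 with an estimated correlation). Btg4, an adaptor of the CCR4-NOT deadenylase, was at least 20100-fold higher, and the storage factor Zar1 rose with 12.44 ± 0.72. The poly(A)-binding protein gene Pabpc1 fell by 5.13 and the helicase Ddx6 by 3.04.

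Pluripotency and translation groups were lower in GV oocytes. Of 24 naive pluripotency genes, 17 fell and 5 rose (camera adjusted p = 2.83e-07, and adjusted p = 0.523 with an estimated correlation). Nanog (chromosome 6, 122707489 to 122714633) measured 0.00723 ± 0.0102 TPM in GV and 884 ± 98.4 TPM in ESC, and Fgf4 was at least 8440-fold lower. Dppa3 and Tcl1, which oocytes also express, rose with log2 fold changes of 8.43 ± 0.5 and 5.11 ± 0.72. Of 12 general pluripotency genes, 9 fell (adjusted p = 0.000393, and adjusted p = 0.664 with an estimated correlation), and Sox2 fell by 7.86. Pou5f1 fell by 1.28, a call lost without GV replicate 1 (−0.65) or ESC replicate 1 (−0.91). In the formative list, 13 of 24 fell and 4 rose (adjusted p = 0.00166, and adjusted p = 0.664 with an estimated correlation), with Nodal at least 3290-fold lower. Fgf5 was near 0 in both groups (log2 fold change −2.6 ± 1.04, adjusted p = 0.0546) and passed with DESeq2 (−2.76), no count filter (−2.34), a replicate block (−2.43) or protein-coding genes alone (−2.7). Of 17 2-cell-like genes, 13 fell and 2 rose (adjusted p = 0.000391, and adjusted p = 0.666 with an estimated correlation). Of 86 cytosolic ribosomal protein genes, 74 fell and 2 rose (adjusted p = 5.53e-09, and adjusted p = 0.666 with an estimated correlation), and Rpl12 fell by 5.79 and Rpl9 by 5.01. Of 13 mitochondrially encoded mRNAs, 8 fell and 5 did not pass (adjusted p = 0.072, 0.0287 without ESC replicate 1 and 0.033 with a replicate block).

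The other lists did not pass camera for GV against ESC (adjusted p in parentheses). Of 78 nuclear oxidative phosphorylation genes, 14 fell and 8 rose (adjusted p = 0.735). Of 14 Wnt targets, 8 fell and 5 rose (0.52), of 13 DNA methylation genes 6 fell and 4 rose (0.545), and of 16 ERK targets 5 fell and 5 rose (0.545). Within them, the oxidase Tet3 rose with a log2 fold change of 3.56 ± 0.41 and Tet2 fell by 7.8. Of 9 reported microRNA-290 and microRNA-302 targets, 5 fell and 1 rose (0.246), and the cell cycle inhibitor Cdkn1a fell by 6.93 and Akt1 at 2.26 ± 0.39. Of 17 reported let-7 targets, 6 fell and 2 rose (0.135), and Igf2bp1 fell by 11.09. Of 16 germ layer genes, 9 fell and 3 rose (0.382). Of 15 extraembryonic genes, 5 fell and 4 rose (0.988), and here the median of −0.31 and the mean of −0.23 ran against the upward direction of the test. Of 15 fibroblast genes, 5 fell and 4 rose (0.988), and of 4 blood genes 1 fell and 2 rose (0.895). Of 21 cumulus and granulosa genes, 7 rose and 2 fell (0.407). Inha, named after its values were seen, measured 4.66 TPM in GV replicate 1 and 105 TPM in GV replicate 2.

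Of 25045 genes tested, 7099 were higher in GV oocytes and 7834 were lower. Adjusted over the list alone, the counts were the same as over all genes except for ribosomal proteins (2 higher, 76 lower), oxidative phosphorylation (4 and 8), the formative list (4 and 14) and granulosa genes (6 and 2). Without GV replicate 1, the genes lower in GV numbered 4922.

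The MII against EpiC comparison asks the same of the later oocyte stage and the later cultured state, and shares no library with the first. The Ago1, Ago2 and Dicer1 mRNAs again differed. Ago3, not called for GV against ESC, passed here, and Ago4 did not (log2 fold change −0.94 ± 0.78, adjusted p = 0.302). Ago2 measured 0.626 ± 0.0674 TPM in MII and 30.2 ± 5.9 TPM in EpiC, a log2 fold change of −4.13 ± 0.36 (adjusted p = 2.03e-05). Ago1 fell by 8.06 on the log2 scale and Ago3 rose, with 78.9 ± 15.9 TPM in MII, 5.72 ± 0.684 TPM in EpiC and a log2 fold change of 4.86 ± 0.55. Dicer1 measured 110 ± 28.2 TPM against 21.3 ± 4.96 TPM (3.83 ± 0.52, adjusted p = 0.0002).

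Of the RISC list, 8 fell, 3 rose and 5 did not pass (camera adjusted p = 0.169). Fxr1 rose with a log2 fold change of 2.95 ± 0.45 and Limd1 with 2.61 ± 0.38, whereas Ajuba fell by 9.72, Mov10 by 4.17 and Fxr2 by 2.21. Of the microRNA biogenesis list, 10 fell, 3 rose and 4 did not pass (adjusted p = 0.246). Tarbp2 fell by 3.25 and Xpo5 by 3.2, to 4.06 ± 1.66 and 2.69 ± 0.709 TPM in MII. Dgcr8 fell by 2.6 and Zcchc11 by 5.87, while Dis3l2, the exonuclease of uridylated RNA, rose with 2.7 ± 0.39. Drosha fell by 2.06, and its call was lost without MII replicate 1 (−1.85) or MII replicate 2 (−1.89).

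Oocyte genes were again higher. Of 28 oocyte markers, 27 rose (camera adjusted p = 7.02e-22, and adjusted p = 0.38 with an estimated correlation), with H1foo at 13900 ± 4770 TPM against 0.0289 ± 0.0409 TPM and Oosp1 at least 254000-fold higher. Btg4 reached 5930 ± 1180 TPM and was at least 324000-fold higher, within a storage and deadenylation list of 24 higher and 8 lower genes (adjusted p = 4.44e-06, and adjusted p = 0.595 with an estimated correlation). Of the meiotic genes, 17 rose and 7 fell (adjusted p = 0.000199, and adjusted p = 0.664 with an estimated correlation). Of the piRNA genes, 13 rose and 3 fell (adjusted p = 0.00393, and adjusted p = 0.666 with an estimated correlation), with Asz1 at 8.31 ± 0.67. Of 13 mitochondrially encoded mRNAs, 11 rose (adjusted p = 0.00179, and adjusted p = 0.666 with an estimated correlation), and mt-Cytb measured 9940 ± 1650 TPM against 2270 ± 396 TPM. Tet3 measured 792 ± 43.4 TPM in MII and 5.33 ± 0.241 TPM in EpiC.

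Ribosomal, respiratory and epiblast groups were lower in MII oocytes. Of 86 ribosomal protein genes, 82 fell and 3 rose (camera adjusted p = 3.4e-22, and adjusted p = 0.664 with an estimated correlation), and Rpl10a fell by 8.25. Of 78 nuclear oxidative phosphorylation genes, 65 fell and 3 rose (adjusted p = 6.87e-08, and adjusted p = 0.666 with an estimated correlation), and Cyc1 fell by 5.97. In the formative list, 18 of 24 fell and 2 rose (adjusted p = 1.45e-05, and adjusted p = 0.533 with an estimated correlation). Fgf5 (chromosome 5, 98254184 to 98277030) measured 0.00504 ± 0.00713 TPM in MII and 37.1 ± 25.8 TPM in EpiC, and Pou3f1 was at least 977-fold lower. Of 17 2-cell-like genes, 14 fell (adjusted p = 2.57e-05, and adjusted p = 0.666 with an estimated correlation), with Zscan4e at least 1380-fold lower. Of 12 general pluripotency genes, 7 fell and 1 rose (adjusted p = 0.0162, and adjusted p = 0.666 with an estimated correlation), a call lost without MII replicate 1 (0.0825) or MII replicate 2 (0.107) and with a replicate block (0.163). Nanog fell by 12.91. Of 24 naive genes, 11 rose and 9 fell (adjusted p = 0.509), with a median of 0.4 and a mean of −0.15. Pou5f1 had a log2 fold change of −0.15 ± 0.4 (adjusted p = 0.747), which was positive with relative log expression, DESeq2 or the length offset and without MII replicate 1 or EpiC replicate 1, and −1.33 and past the threshold with limma on log2(TPM + 1).

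The remaining lists did not pass for MII against EpiC. Counts higher and lower were 4 and 10 for germ layers, 5 and 5 for extraembryonic genes, 2 and 8 for ERK targets, 4 and 7 for Wnt targets and 4 and 6 for DNA methylation. Among their members, the T-box gene T was at least 87.4-fold lower, Dusp6 fell by 7.09 and Ccnd1 by 9.86, while Lef1 rose with a log2 fold change of 4.19 ± 0.59. The ERK list passed without EpiC replicate 2 (adjusted p = 0.038). In the DNA methylation list the median was 0.23 and the mean −0.18. Reported targets of the microRNA-290 and microRNA-302 families were 2 higher and 4 lower, and let-7 targets 4 higher and 8 lower, and Mycn fell by 11.75. Granulosa genes were 6 higher and 6 lower, with Cyp19a1 at 45.9 ± 2.05 TPM in MII. Fibroblast genes were 1 higher and 9 lower, with Tagln at least 1030-fold lower. The 1 higher gene of the blood list, Lyz2, had a log2 fold change of 7.4 ± 2.42, which was −2.29 without MII replicate 1 and lost its call without EpiC replicate 1 (6.88) or EpiC replicate 2 (9.59), with DESeq2 (8.04) and with a replicate block (6.37).

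Of 25045 genes, 7128 were higher in MII oocytes and 9908 lower. Limma on log2(TPM + 1) gave 4380 higher and 9770 lower, so that 31% of its calls were higher against 41.8%. Adjusted over the list alone, counts differed for microRNA biogenesis (4 higher, 10 lower), the formative list (2 and 19), 2-cell-like genes (1 and 14), DNA methylation (5 and 6) and blood (0 and 0). Between the 2 comparisons, 4949 genes were higher in the oocytes of both and 5977 were lower in both, where independent lists would share 2020.4 and 3099.2. Opposite calls were made for 779 genes, where independent lists would give 5038.

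The difference between these comparisons was itself tested, and it passed for 7431 genes. The change from ESC to GV exceeded the change from EpiC to MII for 4116 of them and lay below it for 3315. Tarbp2 and Fxr2 were higher in GV than in ESC and lower in MII than in EpiC, with differences of 4.57 and 3.52 on the log2 scale (adjusted p = 0.00189 and 0.00281). Drosha and Xpo5 were called lower in the MII pair and not in the GV pair, with differences of 2.15 and 2.38 (adjusted p = 0.0431 and 0.0181). Ago3 was called higher in the MII pair and not in the GV pair, with a difference of −3.80 in counts (adjusted p = 0.00421). With an offset for transcript length this difference was −1.29 (adjusted p = 0.107), with limma on log2(TPM + 1) it was −0.16 (0.799), and neither passed. The difference of Drosha ended with relative log expression (adjusted p = 0.0893), DESeq2 (0.0573), the length offset (0.061) and without GV replicate 1 (0.108), either MII replicate (0.103 and 0.0947), either ESC replicate (0.0509 and 0.129) or EpiC replicate 1 (0.152). That of Xpo5 ended without MII replicate 2 (0.0564), ESC replicate 2 (0.0672) or EpiC replicate 1 (0.0545). For Ago2 and Dicer1 the differences of 0.97 and −1.34 did not pass (adjusted p = 0.144 and 0.161), though that of Dicer1 did without GV replicate 1 (0.0191). Limma on log2(TPM + 1) gave 6770 and 2469 genes, 73.3% on the first side against 55.4%. Without ESC replicate 1, 4932 genes passed.

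The MII against GV comparison follows oocytes through maturation. Transcripts for protein synthesis and respiration took a smaller part of the RNA captured in the MII libraries, and mitochondrially encoded mRNAs took a larger one. Whether poly(A) selection was used is not given. Changed poly(A) tails could alter these and other captured shares between GV and MII without a change in the number of molecules. This was not tested. Of 86 ribosomal protein genes, 76 fell and 2 rose (camera adjusted p = 5.97e-19, and adjusted p = 0.666 with an estimated correlation). On TMM-scaled counts, Rps4x fell by 4.83 on the log2 scale and Rps27l rose with a log2 fold change of 2.67 ± 0.33. Rps4x measured 885 ± 31.7 TPM in GV and 13.5 ± 14.1 TPM in MII. Of 78 nuclear oxidative phosphorylation genes, 62 fell and 3 rose (adjusted p = 1.88e-17, and adjusted p = 0.664 with an estimated correlation), and Sdhd fell by 5.04.

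All 13 mitochondrially encoded mRNAs rose (camera adjusted p = 7.85e-13, and adjusted p = 0.523 with an estimated correlation). The mRNA mt-Co2 went from 208 ± 121 to 4750 ± 2460 TPM, and mt-Nd3 had a log2 fold change of 5.18 ± 0.46. Of 37 deadenylation and storage genes, 16 rose and 12 fell (adjusted p = 0.0526, and 0.0473 without MII replicate 1). The deadenylase subunit Pan3 rose with 4.62 ± 0.41, the decapping factor Dcp1a with 4.52 ± 0.39 and Btg4 with 4.16 ± 0.44, while Cnot10 fell by 4.68. Of 27 meiotic genes, 13 rose and 9 fell (adjusted p = 0.0772, and 0.0343 without MII replicate 1). Sgol2a, which protects cohesin, rose with 4.15 ± 0.47 and Fbxo43, an inhibitor of the anaphase-promoting complex, with 3.65 ± 0.5, while Cdk1 fell by 4.94 and Fbxo5 by 4.81. Of 28 oocyte markers, 16 fell and 5 rose (adjusted p = 0.0843), and Zp3 fell by 3.71, Npm2 by 4.04 and Zbed3 up by 3.19 ± 0.39. Of 18 piRNA genes, 9 fell and 1 rose (adjusted p = 0.038, and adjusted p = 0.692 with an estimated correlation). This call was lost without GV replicate 1 (0.122) or MII replicate 2 (0.0513), and with relative log expression (0.0526), a replicate block (0.0967) or protein-coding genes alone (0.0703). Of 15 extraembryonic genes, 6 rose (adjusted p = 0.0439, and adjusted p = 0.666 with an estimated correlation), a call lost without GV replicate 1 (0.124) or MII replicate 2 (0.141) and with protein-coding genes alone (0.119).

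Within the microRNA machinery, the members moved apart during maturation. Of the biogenesis list, 7 rose, 4 fell and 6 did not pass (camera adjusted p = 0.284), and of the RISC list 6 rose, 6 fell and 4 did not pass (adjusted p = 0.954). On TMM-scaled counts, Tarbp2 fell by 4.19 and Fxr2 by 3.57. In TPM, which is scaled otherwise, Tarbp2 measured 154 ± 37.8 in GV and 4.06 ± 1.66 in MII. Fxr2 measured 155 ± 18.4 TPM in GV and 5.74 ± 2.53 TPM in MII. Ago2 fell by 1.7 (adjusted p = 0.00309) and Xpo5 by 2.11 (adjusted p = 0.00495). Drosha fell by 2.1, a call lost without MII replicate 1, at −2.19. The chaperone Hsp90aa1 fell by 4.14, and Ddx5 and Lin28a rose with log2 fold changes of 3.39 ± 0.4 and 4.15 ± 0.63. Ago3 rose with 3.75 ± 0.52 and Dicer1 with 1.81 ± 0.48, but limma on log2(TPM + 1) gave 0.37 and 0.8 and ended both calls. The call of Dicer1 was also lost without GV replicate 2 (1.26) or MII replicate 1 (1.46). Ago1 fell by 2.39, a call that limma on log2(TPM + 1) ended at −0.48. Its mRNA was scarce at both stages, with 0.507 ± 0.345 TPM in GV and 0.0627 ± 0.0173 TPM in MII.

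**Figure D2:**
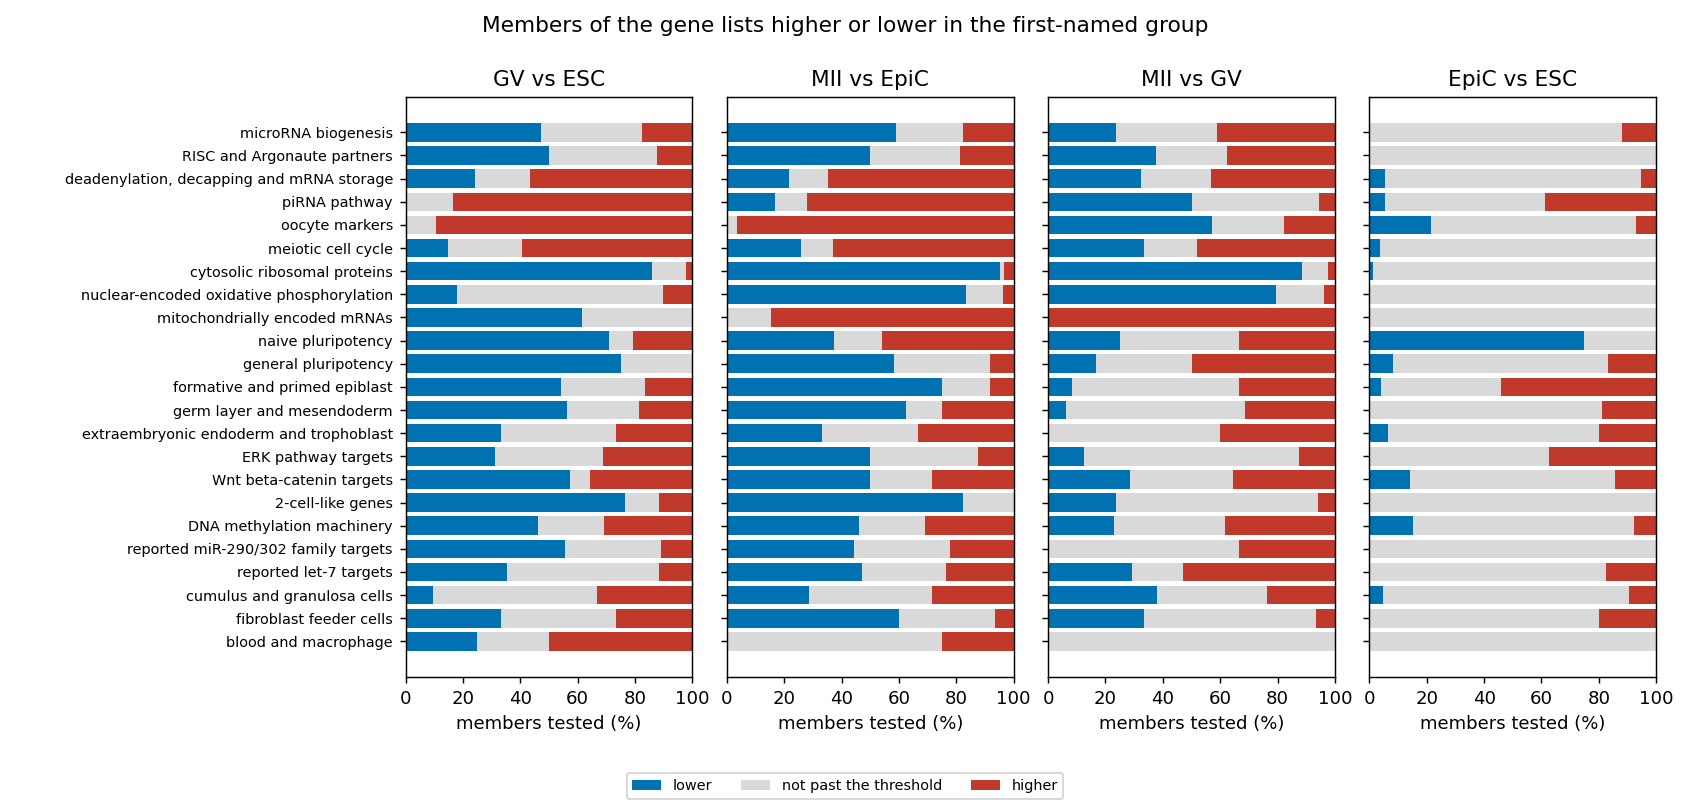
Percent of the tested members of each of the 23 gene lists that were lower (blue), did not pass (grey) or were higher (red) in the first-named group, in the 4 comparisons. For MII against GV, 76 of 86 ribosomal protein genes were lower and 13 of 13 mitochondrially encoded mRNAs were higher.

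Among the largest changes of called protein-coding genes with a mean of at least 20 TPM and no overlap between the groups, the forkhead gene Foxn2, the transcription factor subunit gene Gtf2a1 and the polyadenylation regulator Cpeb4 rose with log2 fold changes of 6.22 ± 0.5, 6.21 ± 0.52 and 6.1 ± 0.49. The proteasome subunit gene Psmb7 fell by 5.47 and Dppa4 by 5.52. Of 13 DNA methylation genes, 5 rose and 3 fell (camera adjusted p = 0.363), with Tet3 at 5.52 ± 0.45 and Zfp57, which fell by 2.38. Of 17 reported let-7 targets, 9 rose and 5 fell (adjusted p = 0.0764, and 0.0287 without MII replicate 1), with Nras at 3.74 ± 0.34. Of 9 reported microRNA-290 and microRNA-302 targets, 3 rose and 6 did not pass (camera adjusted p = 0.124), with Akt1 at 2.87 ± 0.4. Of 21 granulosa genes, 8 fell and 5 rose (camera adjusted p = 0.83), and the median of −1.89 and the mean of −1.31 ran against the upward direction of camera. Amh fell by 7.59, from 0.634 and 3.19 TPM in the GV libraries. In the ERK, Wnt and fibroblast lists, medians of −0.07, −0.61 and −0.09 also ran against an upward test. Counts higher and lower were 2 and 2, 5 and 4, and 1 and 5 there, 8 and 6 for naive, 6 and 2 for general pluripotency, 8 and 2 for formative, 5 and 1 for germ layer and 1 and 4 for 2-cell-like genes, none of which passed camera.

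In all, 4357 genes were higher in MII than in GV and 5572 lower. Limma on log2(TPM + 1) gave 2400 higher and 7327 lower, 24.7% higher against 43.9%, and 194 of the calls had the opposite sign. Adjusted over the list alone, the counts higher and lower differed for biogenesis (7 and 5), RISC (7 and 6), deadenylation (16 and 14), piRNA (2 and 10), ribosomal proteins (3 and 78), oxidative phosphorylation (3 and 66), naive (10 and 7), DNA methylation (5 and 4), let-7 targets (10 and 5) and granulosa genes (8 and 10).

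The EpiC against ESC comparison follows the exit from the LIF and inhibitor condition. By camera at the preset correlation, the naive list moved down and the formative and ERK lists moved up, and with an estimated correlation none of these 3 passed. Of 24 naive genes, 18 fell and 6 did not pass (camera adjusted p = 1.01e-43, and adjusted p = 0.208 with an estimated correlation). The adhesion gene Jam2 fell by 7.54 on the log2 scale, from 290 ± 11.1 to 1.82 ± 0.0281 TPM, Prdm14 by 6.84 and Tcl1 by 6.6. Nanog fell by 2.6, from 884 ± 98.4 to 150 ± 83.3 TPM, a call lost without ESC replicate 1 (−2.53) or EpiC replicate 2 (−2.21).

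Of 24 formative genes, 13 rose, 1 fell and 10 did not pass (camera adjusted p = 8.27e-16, and adjusted p = 0.321 with an estimated correlation). Fgf5 rose from 0.0763 ± 0.0336 to 37.1 ± 25.8 TPM, a log2 fold change of 8.78 ± 0.98. Of 16 ERK targets, 6 rose and 10 did not pass (adjusted p = 1.79e-08, and adjusted p = 0.523 with an estimated correlation), with the phosphatase gene Dusp6 at 6.15 ± 0.79 and Egr1 at 5.94 ± 0.82. Of 12 general pluripotency genes, 2 rose and 1 fell (camera adjusted p = 0.599), and Pou5f1 had a log2 fold change of −0.34 ± 0.4 (adjusted p = 0.85). Of 18 piRNA genes, 7 rose and 1 fell (adjusted p = 0.000107, and adjusted p = 0.664 with an estimated correlation), with Mael at 3.32 ± 0.42. Of 15 fibroblast genes, 3 rose (adjusted p = 2.83e-05, and adjusted p = 0.664 with an estimated correlation). Among them Tagln, an actin-binding protein gene, had a log2 fold change of 6.08 ± 0.89 and lost its call without ESC replicate 1 (5.66). Of 17 reported let-7 targets, 3 rose (adjusted p = 0.00245, and adjusted p = 0.664 with an estimated correlation), among them Lin28a, which blocks let-7 maturation, with 4.06 ± 0.63. A fit on the compared groups alone ended the calls of Lin28a (4.04) and Nanog (−2.57). The let-7 call was lost without ESC replicate 2 (0.166) or EpiC replicate 1 (0.107).

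**Figure D3:**
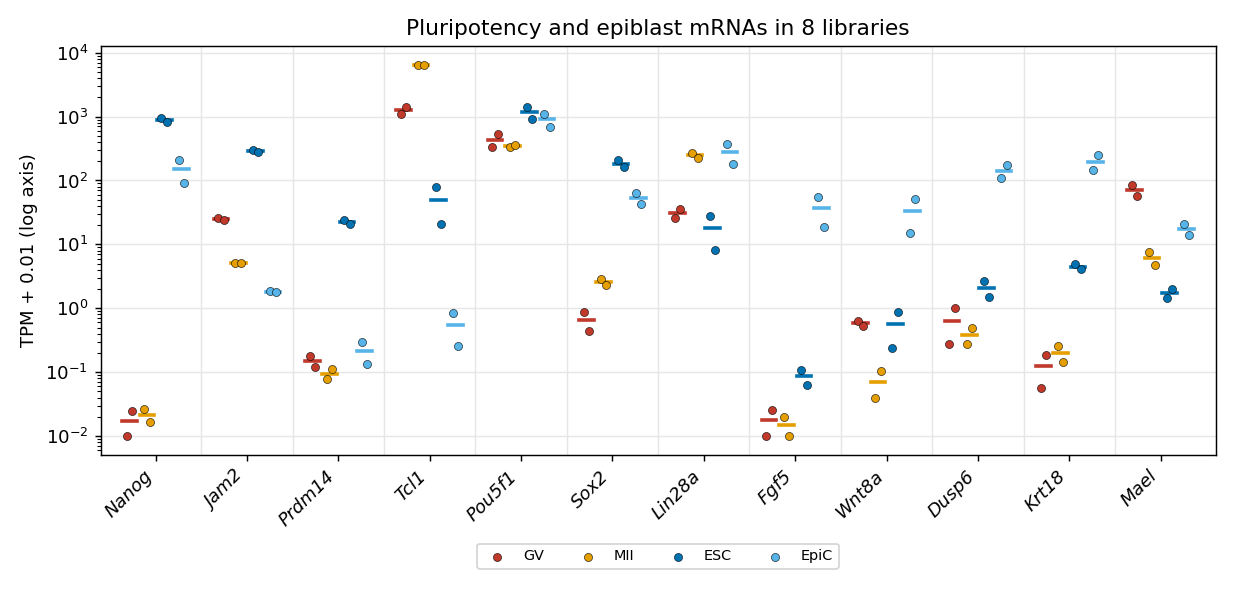
TPM of pluripotency and epiblast genes in the 8 libraries on a log axis, with points for libraries and bars for group means. Nanog falls from 884 TPM in ESC to 150 TPM in EpiC, and Fgf5 rises from 0.0763 to 37.1 TPM.

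The 17 2-cell-like genes moved upward as a list (camera adjusted p = 2.57e-05, and adjusted p = 0.666 with an estimated correlation) with 17 members not passing over all genes and 8 higher when adjusted over the list alone. The 78 oxidative phosphorylation genes moved downward as a list (adjusted p = 0.0497, and adjusted p = 0.848 with an estimated correlation) with a median of −0.21. That call was lost without EpiC replicate 2 (0.937), with relative log expression (0.067), the length offset (0.0514) or protein-coding genes alone (0.114), and ran the other way without ESC replicate 1 (0.936). Genes of the microRNA biogenesis list were 2 higher and 15 not passing (camera adjusted p = 0.213, with that of later lists also in parentheses), and the list passed without ESC replicate 1 (0.0355) or EpiC replicate 2 (0.0246). Ago2 measured 30.2 ± 5.9 TPM in EpiC and 50.7 ± 4.23 TPM in ESC (log2 fold change −0.73 ± 0.32, adjusted p = 0.275), and Dicer1 0.47 ± 0.47 (adjusted p = 0.786). Germ layer genes were 3 higher (0.185, and 0.0297 without ESC replicate 1 or 0.0392 without EpiC replicate 2). Wnt targets were 2 higher and 2 lower (0.39), and the Wnt inhibitor Notum fell by 6.63, and DNA methylation genes 1 higher and 2 lower (0.223), and Tet2 fell by 3.86. Extraembryonic genes were 3 higher and 1 lower (0.358), with the keratin gene Krt18 at 5.55 ± 0.65 and Lama1, which fell by 3.97. Granulosa genes were 2 higher and 1 lower (0.407), with the hyaluronan synthase gene Has2 at 6.82 ± 0.75. Oocyte markers were 2 higher and 6 lower (0.133), and Kit fell by 4.79, a median of 0.12 and a mean of −0.69. Deadenylation genes were 2 higher and 2 lower (0.641), with Cpeb1 at 2.94 ± 0.39, and meiotic genes 1 lower (0.823), Aurkc by 2.82. In the meiotic list the mean of 0.09 ran against the downward test, as did medians of 0.02 for ribosomal proteins (0.906) and 0.07 for microRNA-290 and microRNA-302 targets (0.934). RISC (0.578), mitochondrially encoded (0.954) and blood genes (0.735) did not pass either.

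Of 25045 genes, 659 were higher in EpiC and 708 lower in a model that does not pair libraries, and 2017 passed with a block for the replicate number. Fewer genes passed when a library was left out, 409 without ESC replicate 1, 753 without ESC replicate 2, 758 without EpiC replicate 1 and 827 without EpiC replicate 2. Among called protein-coding genes with a mean of at least 20 TPM and no overlap between the groups, the largest falls included these: Cd3g was at least 552-fold lower, Crxos fell by 9.53 and the aquaporin gene Aqp3 fell by 7.15. The largest rises under the same limits were Vrtn with 9.85 ± 0.86 and the carbonic anhydrase gene Car4 with 9.03 ± 0.73. Adjusted over the list alone, the counts higher and lower differed for naive (1 and 22), formative (18 and 1), ERK (11 and 0), piRNA (9 and 4), fibroblast (5 and 0), let-7 (4 and 0), germ layer (6 and 4), extraembryonic (3 and 2), Wnt (4 and 3), DNA methylation (2 and 4), deadenylation (2 and 4), granulosa (3 and 1) and RISC (1 and 1).

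Transcript usage asked which isoforms of the machinery each group carried. Ago3 (ENSMUSG00000028842.15, chromosome 4, 126331704 to 126429556) used its transcripts differently between GV and ESC (gene-level adjusted p = 0.0172). Ago3-001, a coding transcript of 15595 bases, held 4.27 ± 1.96% of the gene's TPM in GV, 31.7 ± 5.05% in MII, 52.2 ± 1.98% in ESC and 40.2 ± 8.72% in EpiC (SD, n = 2). Of the gene's estimated counts, which weigh long transcripts more, it held 57.4%, 94%, 97.4% and 95.6%, and its own test for GV against ESC did not pass (relative log2 fold change −0.49, adjusted p = 0.634). Processed transcripts that are annotated as noncoding, Ago3-004 and Ago3-006, held 41.6 ± 5.62% and 40.3 ± 7.32% of the TPM and 18.1% and 17.8% of the counts in GV, and passed against ESC (adjusted p = 0.0443 and 0.0107). For MII against GV and MII against EpiC the gene did not pass (adjusted p = 0.0575 and 0.0969). Drosha-002 held 29.7 ± 3.76% in GV and 0% in both MII libraries (gene-level adjusted p = 0.00025 for MII against GV). Tnrc6a-005 held 9.92 ± 5.15% in GV and near 0% in MII (gene-level adjusted p = 0.0026). Ago2, Dicer1 and Tnrc6b had 1 listed transcript each, so these tables hold no share for a shorter Dicer1 form.

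**Figure D4:**
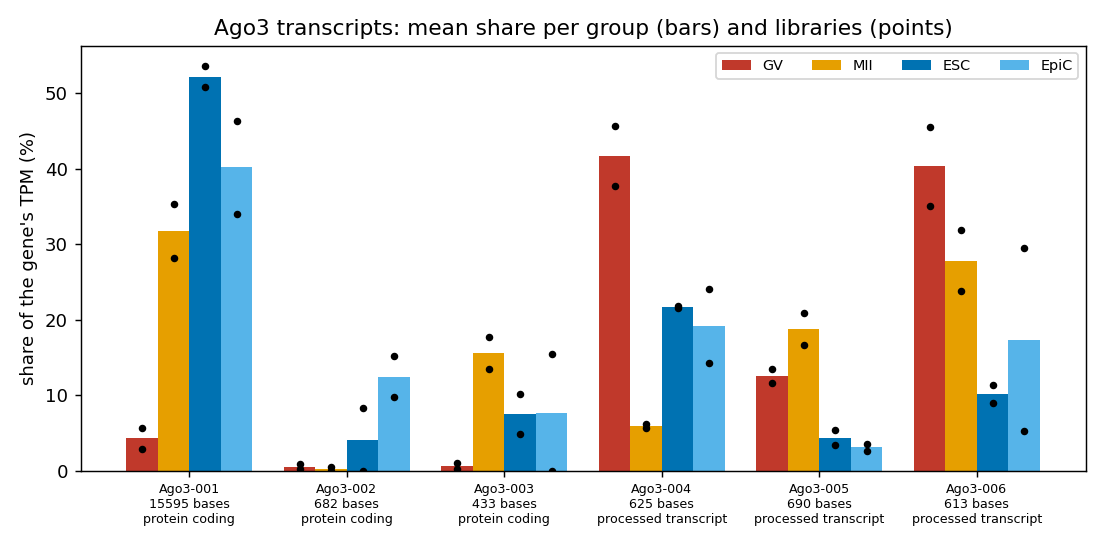
Percent of the Ago3 gene's TPM held by each of its 6 listed transcripts, with bars for group means and points for libraries. Ago3-001 holds 4.27% in GV and 52.2% in ESC, against 57.4% and 97.4% of the counts, and its own test did not pass (adjusted p = 0.634).

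Other genes met the rule on shares, and adjusted p-values are again those of the gene. The splicing kinase gene Srpk1 (chromosome 17, 28587648 to 28622709) went from 26.7 ± 9.26% to 99.3 ± 0.187% of Srpk1-001 between GV and MII, while Srpk1-002, annotated for nonsense-mediated decay, went from 48.3 ± 3.05% to 0% (adjusted p = 9.62e-11). Gnb4-001 went from 5.13 ± 1.96% to 81.9 ± 8.34% and Dcun1d1-201 from 6.27 ± 0.87% to 53.1 ± 5.34% (adjusted p = 4.52e-06 each). Mdm4-003 held 68.1 ± 5.08% in GV and 0% in ESC, and Eif4a2-014 59.5 ± 5.93% against 3.69 ± 0.181% (adjusted p = 1.65e-07 each). Rere-003 held 0% in MII and 30.3 ± 2.16% in EpiC, and Rev1-001 95.7 ± 0.721% against 55.1 ± 4.58% (adjusted p = 5.37e-10 each). Coil-001 went from 96.1 ± 1.94% in ESC to 6.32 ± 1.2% in EpiC and Coil-201 from 0% to 87.8 ± 4.42% (adjusted p = 0.000415). The own tests of Srpk1-001, Gnb4-001, Dcun1d1-201, Rev1-001 and Coil-001 did not pass in these contrasts (adjusted p = 0.778, 0.141, 0.116, 0.818 and 0.0716). Of 11953 genes, 2937 passed for GV against ESC, 3586 for MII against EpiC, 660 for MII against GV and 11 for EpiC against ESC. The counts moved by more than 1.5 times when a library was left out. For GV against ESC they were 573 and 673 without GV replicate 1 or 2, and 1503 and 752 without ESC replicate 1 or 2. For MII against EpiC they were 1755 and 1192 without MII replicate 1 or 2, and 2016 without EpiC replicate 2. For MII against GV they were 364 and 294 without GV replicate 1 or 2, and 247 and 270 without MII replicate 1 or 2. For EpiC against ESC they were 20 and 7 without ESC replicate 1 or 2, and 35 without EpiC replicate 1.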

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

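The test of the difference between the 2 oocyte-against-culture comparisons was planned, and no explanation was tested here. By construction, this difference also equals the EpiC against ESC change minus the MII against GV change. For EpiC against ESC, 2 of 17 biogenesis genes and 0 of 16 RISC genes were called. For MII against GV, 7 biogenesis genes rose and 4 fell, and 6 RISC genes rose and 6 fell. The differences of machinery genes are therefore not separate from the changes between GV and MII given above. What drew attention is that the same contrast, oocytes against cultured cells, differed between the earlier pair of groups (GV and ESC) and the later pair (MII and EpiC) for 7431 genes by the edgeR quasi-likelihood test of the difference. Among the 33 genes of the microRNA biogenesis and RISC lists, 15 passed that test. Values are the log2 fold change of GV against ESC minus that of MII against EpiC. On the positive side, where the MII pair lay lower, were Tarbp2 (4.57), Fxr2 (3.52), Hsp90aa1 (3.48), Wtip (2.53), Ago1 (2.46), Xpo5 (2.38), Drosha (2.15) and Srrt (1.85). On the negative side, where the MII pair lay higher, were Ago3 (−3.80), Ddx5 (−3.42), Dis3l2 (−3.36), Fxr1 (−2.66), Fmr1 (−2.53), Ddx17 (−2.48) and Hsp90ab1 (−2.00). At the gene level, the difference of Ago3 passed on counts. It was −1.29 with an offset for transcript length (adjusted p = 0.107) and −0.16 with limma on log2(TPM + 1) (0.799), and neither passed. The coding transcript Ago3-001 alone measured 2.69 ± 1.63 TPM in GV and 25.4 ± 9.02 TPM in MII. In ESC and EpiC it measured 2.56 ± 0.825 and 2.33 ± 0.773 TPM. Its own difference between the pairs was not tested. Ago1 was scarce in both oocyte groups, with 0.507 ± 0.345 TPM in GV and 0.0627 ± 0.0173 TPM in MII. The calls of Tarbp2, Fxr2, Ddx5, Ddx17 and Dis3l2 held under each alternative run. The length offset also ended the calls of Drosha (1.94), Ago1 (1.98) and Wtip (2.21). Limma on log2(TPM + 1) ended those of Ago1 (0.57), Fmr1 (−1.21), Fxr1 (−1.43) and Hsp90ab1 (−0.85), and relative log expression and DESeq2 that of Drosha (1.93). A test against a fold of 2 ended those of Drosha, Xpo5, Srrt, Ago1, Wtip, Fmr1 and Hsp90ab1. With 1 library left out, the calls of Drosha, Xpo5, Srrt, Ago1, Wtip, Fmr1, Hsp90aa1 and Hsp90ab1 ended at least once. Those libraries were GV replicate 1 (Drosha 1.83, Hsp90ab1 −1.76), GV replicate 2 (Ago1 1.45, Wtip 2.08, Fmr1 −2.10, Hsp90ab1 −2.14), MII replicate 1 (Drosha 2.22, Ago1 2.69, Fmr1 −2.15, Hsp90aa1 3.25, Hsp90ab1 −2.14) and MII replicate 2 (Drosha 2.25, Xpo5 2.25, Ago1 2.38, Hsp90ab1 −1.63). They were also ESC replicate 1 (Drosha 2.58, Srrt 1.84, Ago1 2.60, Wtip 2.51, Fmr1 −2.17, Hsp90ab1 −1.62), ESC replicate 2 (Drosha 1.81, Xpo5 2.10, Srrt 1.85, Ago1 2.32, Wtip 2.54), EpiC replicate 1 (Drosha 1.36, Xpo5 1.84) and EpiC replicate 2 (Wtip 2.41, Fmr1 −2.15, Hsp90ab1 −1.68). For genes across the genome, limma on log2(TPM + 1) put 6770 genes on the positive side and 2469 on the negative side, against 4116 and 3315 with TMM, 3985 and 3594 with relative log expression and 4792 and 4282 with DESeq2. That limma run differs from the others in its unit and filter as well as its scaling, and these were not separated. Without ESC replicate 1, 4932 genes passed.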

How the results depend on the processing

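The run on protein-coding genes alone was chosen after seeing the data, and the other alternatives were planned. Named genes kept direction and side of the threshold in 3244 values under the alternatives, lost the call in 128, gained one in 10 and turned in 15. Of the 15, 1 had a call, Lyz2 for MII against EpiC (−2.29 without MII replicate 1 to 9.59 without EpiC replicate 2). The other 14, without a call, were Ago4 for GV against ESC (0.07 with no count filter, −0.53 to 0.23 with 1 library left out) and MII against EpiC (−1.51 to 0.02), Drosha for GV against ESC (−0.21 with limma, −0.25 to 0.52) and Pou5f1 for MII against EpiC (0.03 with relative log expression and DESeq2, 0.09 with the length offset, −0.36 to 0.09), MII against GV (−0.29 with limma) and EpiC against ESC (−0.65 to 0.02). Gene lists kept both in 730 values, lost the call in 49, gained one in 11 and turned in 34. Of the 34, 1 had a call, nuclear-encoded oxidative phosphorylation for EpiC against ESC (adjusted p = 0.936 without ESC replicate 1, and 1.64e-05 without EpiC replicate 1 to 0.937 without EpiC replicate 2). For EpiC against ESC, 1367 genes became 2953 with DESeq2, 2580 with no count filter, 2332 with limma on log2(TPM + 1), 833 on the compared groups alone and 718 against a fold of 2. Changed transcript usage, of 2937, 3586, 660 and 11 genes, became 5949, 5380, 1553 and 96 with limma voom and diffSplice, in the order GV against ESC, MII against EpiC, MII against GV and EpiC against ESC. Camera called 9, 10, 5 and 8 lists, and with an estimated correlation 0 lists in each of the 4 comparisons at the adjusted threshold, with 3, 1, 1 and 3 at an unadjusted p under 0.05, while fry called 16, 15, 8 and 6. For MII against GV, 5 list calls became 2 with protein-coding genes alone. That run also left out mitochondrially encoded and replication histone genes, so the mitochondrially encoded list was absent, and the piRNA and extraembryonic calls ended (adjusted p = 0.0703 and 0.119). Except where the construction of an alternative shows it, the cause was not tested.

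Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, gave 11366 to 12925 genes for GV against ESC, 13612 to 16212 for MII against EpiC, 7089 to 8317 for MII against GV, 409 to 827 for EpiC against ESC and 4932 to 6644 for the difference. Transcript usage ran from 573 to 1503, 1192 to 2795, 247 to 364 and 7 to 35 genes. List calls ran from 9 to 10, 9 to 11, 3 to 8 and 7 to 9. A block for the replicate number gave 16388, 18035, 11115 and 2017 genes and 8693 for the difference. The numbers do not pair all samples, since the deviations of replicates correlated across genes at 0.771 between ESC and EpiC and 0.406 between GV and MII, but at 0.0623 to 0.105 between oocytes and cultured cells. Small changes are at the limit of 2 libraries per group, since a simulation with 50 genes per fold recovered 18% to 30% of 4-fold changes over the 4 comparisons. The planned simulation recovered 1.5% of them for MII against GV and 0% in the other comparisons. The dense simulation recovered 64.7%, 69%, 69.5% and 32.2% of 4- to 8-fold changes and 37.3%, 39.7%, 30.9% and 8.8% of 2- to 4-fold changes. Of changes over 16-fold it recovered 91.5%, 86.3%, 40.9% and 45.2%. Large changes were therefore missed too, and the cause was not tested.

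The other 33 list values that turned had no call, given as adjusted p with the range over left-out libraries. For GV against ESC they were oxidative phosphorylation (0.312 to 0.608), extraembryonic (0.966 with protein-coding genes alone, 0.744 to 0.967) and fibroblast (0.973, 0.368 to 0.986). For MII against EpiC they were DNA methylation (0.537 to 0.897) and microRNA-290 and microRNA-302 targets (0.989 with relative log expression, 0.706 to 0.979). For MII against GV they were RISC (0.989 with relative log expression, 0.95 with a block, 0.732 to 0.898), ERK (0.154 to 0.973), granulosa (0.368 to 0.775), fibroblast (0.406 to 0.937) and blood (0.406 to 0.859). For EpiC against ESC they were deadenylation (0.0748 to 0.696), meiotic (0.268 to 0.685), ribosomal (0.107 to 0.524), mitochondrially encoded (0.956 with a block, 0.526 to 0.632), general pluripotency (0.0992 to 0.696), DNA methylation (0.058 to 0.851) and microRNA-290 and microRNA-302 targets (0.886 with the length offset, 0.545 to 0.912).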

Other observations

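The 7 families and the transcript classes described first were chosen after the result was seen, as were all tests of this part except those of the microRNA sites and of the polyadenylation element against permuted words. Of 39 proteasome subunit genes, 23 fell and 2 rose, with a median log2 fold change of −2.47 against 0.65 in random lists matched on expression (permutation p = 0.0001, one-sided, the smallest that 10000 lists can give). Psmc2 fell by 5 and Psmc1 by 4.61, whereas Psmd3 rose with 2.78 ± 0.42 (SE), these and the members below all named after their values were seen. Mitochondrial ribosomal protein genes numbered 52 lower and 5 higher of 77 (median −2.52, permutation p = 0.0001, again the smallest possible), and Mrpl46 fell by 4.84 while Mrpl3 had 2.93 ± 0.32. Subunit genes of initiation factor 3 numbered 10 lower and 1 higher of 12 (median −3, permutation p = 0.0016), and Eif3m fell by 4.96 while Eif3i had 2.35 ± 0.35. Nop and Utp genes of ribosome assembly numbered 8 lower and 3 higher of 16 (median −1.89, permutation p = 0.033). Spliceosomal genes numbered 13 higher and 10 lower of 35 (median 0.48, which turned to −0.51 with limma on log2(TPM + 1), permutation p = 0.49), Zfp genes 66 and 102 of 332 (median −0.53, p = 0.7) and Kif genes 12 and 7 of 35 (median 0.03, which turned to −0.09 with limma, −0.1 without GV replicate 1 and −0.24 without MII replicate 2, p = 0.74), each a permutation p on the lower side. Under relative log expression, DESeq2, the length offset, limma on log2(TPM + 1) and without each GV or MII library, the medians stayed negative, from −2.94 to −1.81 for the proteasome, −3.23 to −2.1 for mitochondrial ribosomal, −3.65 to −2.79 for initiation factor 3 and −3.25 (without MII replicate 2) to −1.47 (without MII replicate 1) for Nop and Utp genes. The permutation p-values treat genes as independent and were not adjusted over the 7 families, so they may be too small. With correlations between genes estimated from the data, 0.593 for ribosomal protein genes and 0.437 for oxidative phosphorylation genes, neither of these lists passed for MII against GV (adjusted p = 0.666 and 0.664), and the families were not tested in that way.

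Transcripts annotated as retaining an intron held 3.34 ± 0.193% of the TPM in GV, 2.09 ± 0.124% in MII, 5.07 ± 0.578% in ESC and 4.4 ± 0.0711% in EpiC (SD, n = 2). The gap between the lower GV library and the higher MII library was 1.03%, where the replicates of GV and of MII differed by at most 0.273%. Gene models of the TEC class, which await experimental proof, held 6.3 ± 0.363% of the TPM in GV and 0.329 ± 0.0744% in MII. The 8 most abundant of 2639 such transcripts held 5.41% in GV and 0.134% in MII. Of these, Gm42887 and Gm36976, named after their values were seen, measured 12100 ± 764 and 8290 ± 55.8 TPM in GV, and 325 ± 150 and 204 ± 88.5 TPM in MII. Gm37110 and Gm44183 have an identical sequence of 1628 bases, so their reads cannot be separated.

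Sites of microRNAs in 3′ UTRs were tested as a hypothesis. If the microRNA-290 and microRNA-302 families held their targets lower in ESC than in GV oocytes, genes with the 7-base site should lie higher in GV. The coefficient of the site was 0.0399 on the log2 scale for GV against ESC, against a median of 0.0924 for permuted words (permutation p = 0.63, one-sided), and 0.093 for MII against EpiC (p = 0.46). If let-7 held its targets lower in GV oocytes, its coefficient for GV against ESC should be negative, and it was −0.0274 (permutation p = 0.19, one-sided, lower). None of these coefficients lay outside the range of permuted words. With the extreme permuted words left out, this range was −0.513 to 0.616 for the microRNA-290 and microRNA-302 site in GV against ESC. In MII against EpiC it was −0.609 to 0.732, and for let-7 in GV against ESC −0.165 to 0.367. A coefficient of 0.3 for the microRNA-290 and microRNA-302 site would lie inside both of its ranges. Effects inside these ranges may be missed, so the hypotheses cannot be told apart from their absence here. Over 16 tests of words, the lowest adjusted two-sided p was 0.711.

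The cytoplasmic polyadenylation element TTTTAAT was tested in the same way. Its coefficient for MII against GV was 0.976, above all 14 permuted words, with a permutation p of 0.067, the smallest that 14 words allow, so this test alone leaves the question open. Against 114 other words of A and T alone, of which the highest reached 0.8, the permutation p was 0.0087, the smallest possible. This argues against any word of A and T giving the same coefficient. It does not exclude base composition, since the 114 words mix A and T in any proportion and words close to the element were left out. Their median was 0.25, against 0.434 for the permuted words of the same letters. The related word TTTTATT had a coefficient of 0.847, which none of the 114 words reached either. A candidate explanation, found and tested on the same data, is that mRNAs with the element kept or gained share during maturation. Longer poly(A) tails could also raise the share captured in a library without a change in the number of molecules, and this was not tested.

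Granulosa markers differed between the GV libraries, in a list fixed before the data were examined. Of 14 listed markers with a mean of at least 0.5 TPM in GV, 11 were higher in replicate 2, and the median log2 ratio of replicate 2 over replicate 1 was 2.46, where random lists matched on expression had a median of −0.06 (permutation p = 0.0001, one-sided, the smallest possible). That p treats genes as independent and sets 1 library against 1 library, so it does not measure the spread between oocyte samples. The listed marker Kitl went the other way, at 2.94 TPM in replicate 1 and 0.979 TPM in replicate 2. TPM is a share of each library, so a difference in depth alone would shift genes of the same expression alike, and it is argued against, since the upper bound of the 95% range of these random lists was 0.35. This comparison was chosen after the result was seen. RNA of granulosa or cumulus cells in GV replicate 2 may be the source, with Inha at 4.66 and 105 TPM, Inhbb at 0.282 and 33.3 TPM, Fst at 0.699 and 17.9 TPM and the abundant Serpine2 at 197 and 260 TPM in replicates 1 and 2. Serpine2 reached 423 and 715 TPM in MII, so it does not mark these cells alone. Of the 21 listed genes, 5 reached 1 TPM in both MII libraries and 1 stood in another list, and a difference between the oocytes themselves was not tested.

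Ribosomal and small structural RNA differed between replicate numbers. Gm42418 and Rn7sk, named after their values were seen, had a higher TPM in replicate 2 in 8 of 8 pairs of gene and group. In replicates 1 and 2, Gm42418 measured 213 and 170000 TPM in EpiC and 204 and 13300 TPM in GV, and Rn7sk 7.99 and 381 TPM in EpiC and 25.9 and 31.2 TPM in MII. TPM is already a share, so depth alone predicts a ratio of 1, and it is argued against for Gm42418, whose ratios were 19.3 to 798, up to 327 times the ratio of depths. For Rn7sk the ratios were 2.02, 1.2, 27.3 and 47.7 in GV, MII, ESC and EpiC. A preparation that kept more RNA without a poly(A) tail in replicate 2 may account for it, and stays open because the labels give no preparation per library.

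The fibroblast list moved up from ESC to EpiC by camera at the preset correlation, with 3 of 15 genes higher and 12 not passing, and did not pass with an estimated correlation (adjusted p = 0.664). RNA of fibroblasts is argued against as the main source of Tagln. The mean of Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, was 0.397 TPM in EpiC, 0.408% of the 97.2 TPM of Tagln. This ratio cannot exclude a low level of fibroblast RNA behind the other listed genes. After Tagln (134 and 60 TPM in the EpiC replicates), Twist1 measured 7 and 4.73 TPM and Dcn 4.78 and 0.674 TPM. Expression of Tagln by the EpiC themselves may be the source, and remains a hypothesis. Of the 16 listed genes, 2 reached 1 TPM in both ESC libraries and 0 stood in another list.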
